A study of Mus musculus with 2 samples.

How the data were processed

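The deposited matrices hold raw UMI counts for 32285 genes, made with Cell Ranger 7.0.1 per the file headers, on GRCm38 per the submitters' processing notes; the 10x chemistry and the annotation release are not given in the sources used here. Per the labels' protocols, the anterior segment was dissected, tissue other than cornea and limbus was removed as far as possible, and cells were freed with liberase and then trypsin at 37 °C. Gene symbols come from the deposited gene tables, and coordinates from GENCODE M21, which matched 32235 genes by Ensembl ID and left 50 unmatched. The groups, the contrast, the gene lists, the rule for named genes and, except where stated, the alternatives were fixed before the data were examined. All samples were used, 1 uninjured and 1 NaOH-injured library.

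Cells with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, 7150 of 7490 barcodes in the uninjured and 9003 of 9399 in the injured library; 334 and 392 of those removed were over the mitochondrial limit. Doublets were scored in each library with Scrublet as provided in scanpy. Its automatic threshold marked 32 and 3 cells, 0.448% and 0.0333%, which was taken as a failure of the threshold, and each library's highest scores were removed instead at an assumed 0.8% per 1000 barcodes, 5.99% and 7.52% (375 and 657 cells). This rate was chosen after seeing the data in place of the caller's own threshold, which is among the alternatives. Analysed cells numbered 6775 and 8346, with 77816659 and 96375562 UMIs.

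Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave the clusters of both libraries together, with no batch correction. Clusters were named by marker genes listed beforehand, of which at least 3 had to be detected, and kept unnamed if shallow or if markers of another class led; names carry the ending -like. Non-epithelial cells were clustered again with 20 components to describe sub-clusters, a step chosen after seeing the data. Classes of at least 50 cells in each library were compared (epithelial, stromal, mural and Schwann), and after seeing the data those of at least 10 cells (vascular endothelial, macrophage or monocyte) were added.

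Raw counts were summed per class and library and divided by the class total to give CPM. Ratios are injured over uninjured, and counts under 3 over a class were set to 3 for the ratio. The same was done for sums of thinned cells, so a ratio there with a count under 3 is a limit and not an estimate. Intervals of levels and ratios are exact Poisson and conditional binomial intervals, and those of shares exact binomial intervals, all at 95%. They treat UMIs or cells as independent and hold no variation between mice. No test was made, because each group has 1 library. The named genes of a class are the 12 with the largest ratio in each direction among genes of at least 100 CPM in 1 library whose level is at least 25% of that in the class where the gene is highest; members of gene lists are named where they are among those with the largest ratio and reach 50 CPM. Genes so named had a ratio of at least 2 in their class and were ranked by log2 ratio; mitochondrial, ribosomal, hemoglobin, sex-linked and predicted genes and the markers of the class itself were left out. Of 144 genes named by this rule 4 are not reported here, and counts over alternatives cover the other 140. Some members of fixed lists or pairs that are given with their values also served to name a class, among them Krt12, Aldh3a1, Krt5, Krt14, Kera, Dcn, Lum, Col1a1, Col3a1, Pdgfra, Kdr, Flt1, Csf1r and Cxcr2. A list member counted as higher or lower at a ratio of at least 2 with an interval of the ratio that excluded 1. A total of 42 gene lists and 54 ligand and receptor pairs were fixed beforehand. A list was measured from members with at least 20 UMIs over both libraries and needed 4 of them; its median carries an interval from the order of its members, and its percentile is the place among 10000 random lists matched by expression in 20 bins, which ignores correlation between genes and is a description only. Of 208 list medians measured over the 6 classes, 66 are described; which to describe was decided after the values were seen, so their percentiles are those of a selection. Members below 25% of their level in the highest class were counted as being at free RNA levels, which does not show their source. Counts of higher and lower members include them; 299 of 375 such members of the described lists lay above that level. Cycling cells are those with at least 2 listed cell cycle genes after thinning to 1000 UMIs.

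The calling of genes by the interval and a 2-fold limit was tried on simulated counts with 200 altered genes, 50 per fold size. Among 14631 epithelial genes tested 44, 96, 100 and 100% were called at 2, 4, 8 and 16-fold, with 0.319% called among unaltered genes. The values were 46, 98, 100 and 100% among 11995 stromal genes, with 0.822%. They were 36, 80, 90 and 96% among 4544 mural genes, with 1.75%, and 36, 82, 86 and 94% among 3083 Schwann genes, with 4.02%. They were 18, 78, 86 and 82% among 7747 vascular genes, with 1.63%, and 8, 50, 64 and 84% among 7159 macrophage genes, with 2.01%. The simulation holds counting error alone.

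Alternatives were a stricter filter (500 genes, 1000 UMIs, 10% mitochondrial), no filter, doublets kept, the automatic doublet threshold, resolutions 0.5 and 2, 15 components, each library clustered on its own, stress and cycle genes left out of the clustering, scaling by trimmed means (TMM), totals without the 50 most abundant genes, means over cells, cells thinned to 1000 UMIs, other minima of UMIs per list member, members at free RNA levels left out, and sub-clusters of other names left out. The last of these and the automatic threshold were added after seeing the data. Velocity, ligand and receptor scores and trajectory analysis were not used here. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.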

Results

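Single-cell transcriptomes were compared between the cornea and limbus, the rim of tissue around the cornea, of 1 uninjured wild-type mouse and 1 wild-type mouse whose eye was burned with sodium hydroxide (NaOH). The study asks which signalling pathways an alkali burn of the cornea engages. The time between injury and collection is not given in the sources used here. Droplet-based 10x Genomics libraries gave 7490 barcodes and 85457541 UMIs (unique molecular identifiers, each standing for 1 captured transcript) in the uninjured library, and 9399 barcodes and 108863350 UMIs in the injured library. After filtering, 6775 uninjured and 8346 injured cells were analysed, with medians of 10162 and 10599 UMIs and of 2499 and 2626 genes per cell. With 1 library per group no difference has a replicate check and no test was made. Levels are given on the CPM scale, UMIs of the gene over all UMIs of its cell class, and the 95% intervals, exact Poisson for levels and ratios and exact binomial (Clopper-Pearson) for shares, cover counting error only.

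Neutrophil-like cells, the first granulocytes to enter injured tissue, made up 12.2% of the injured library (95% interval 11.5 to 12.9, 1020 cells) and 0.0295% of the uninjured library (0.00358 to 0.107, 2 cells). Macrophage or monocyte-like cells made up 4.33% (3.899 to 4.78) against 0.251% (0.146 to 0.401), and vascular endothelial-like cells 2.54% (2.21 to 2.90) against 0.620% (0.447 to 0.837). Stromal-like cells, which include the keratocytes that build the corneal matrix, made up 9.62% (8.997 to 10.3) against 6.77% (6.19 to 7.40). Epithelial-like cells were the largest class in both libraries, at 69.0% (68.0 to 70.0) injured and 78.0% (77.0 to 79.0) uninjured, and the intervals of the mural-like and Schwann-like shares overlapped between the libraries. A further 12.6% of uninjured cells (11.9 to 13.4), against 0.132% of injured cells (0.0658 to 0.236), fell in clusters 11 and 17, with epithelial markers but a median of 1131 and 1068 UMIs, and stayed unnamed. The neutrophil-like cells were shallow, with a median of 852.5 UMIs, and their share of the injured library was 3.23% under a stricter filter of at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Shares also depend on the dissection, which removed the lens, retina, iris and most of the conjunctiva, and on digestion of the tissue.

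**Figure D1:**
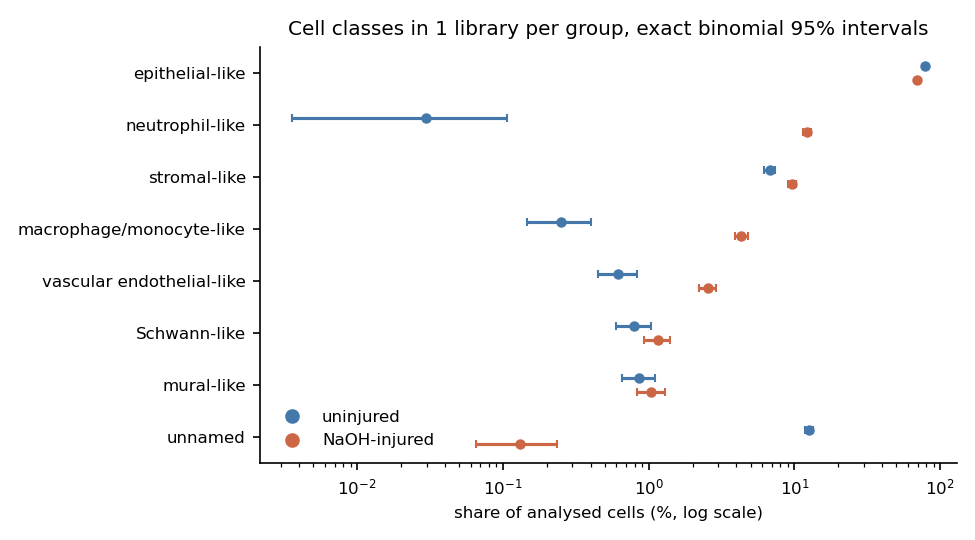
Share of analysed cells in each class on a log axis, in percent, for the uninjured (blue) and NaOH-injured (red) library, 1 library each; points are shares and bars exact binomial 95% intervals that cover counting error only. Neutrophil-like cells stood at 12.2% in the injured and 0.0295% in the uninjured library.

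The epithelium of the injured library held far fewer transcripts of the genes that mark mature corneal epithelium. Krt12, the cornea-specific keratin, stood at 19620 CPM (19588 to 19652) in the uninjured and 27.0 CPM (25.8 to 28.1) in the injured epithelial-like cells, 727-fold lower (697 to 759). Slurp1, which encodes a secreted Ly6-family protein of the corneal surface, stood at 4432 CPM in the uninjured cells and was counted 4 times in all injured epithelial cells, 0.0498 CPM (0.0136 to 0.127). The Ly6-family gene Lypd2 showed the same values in the injured cells against 6144 CPM in the uninjured. These genes are neighbours in the GRCm38 annotation: Slurp1 (ENSMUSG00000022596) lies on chromosome 15, 74724318 to 74728034, minus strand, and Lypd2 (ENSMUSG00000022595) on chromosome 15, 74732247 to 74734329, minus strand. The corneal crystallins Aldh3a1, an aldehyde dehydrogenase, and Tkt, transketolase, were 33.1-fold (32.6 to 33.5) and 7.55-fold (7.48 to 7.63) lower. The urothelial plaque gene Upk1b was 8.25-fold lower (7.96 to 8.54), and Pax6, the transcription factor that directs eye development, 2.41-fold lower (2.34 to 2.49). Clu, the secreted chaperone clusterin, stood at 3072 against 190.0 CPM, 16.2-fold higher (15.9 to 16.4). Of the 11 measured corneal identity genes 6 were at least 2-fold lower and 1 was at least 2-fold higher; in this and the following gene lists, whose members were fixed beforehand, higher and lower mean at least 2-fold with an interval that excludes 1. Krt12 and Aldh3a1 were also among the markers that named the class. Their median log2 ratio was -1.27 (-9.51 to 0.04), percentile 0 among 10000 random lists of matched expression. The transcription factors Klf4 and Klf5 of the same list had log2 ratios of -0.10 and 0.04.

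**Figure D2:**
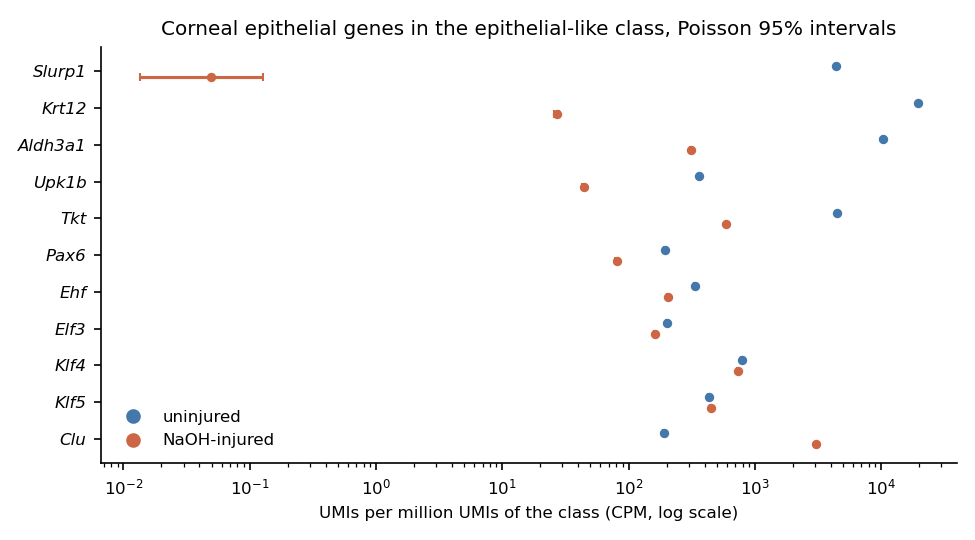
Levels of the corneal epithelial identity genes in epithelial-like cells, in CPM on a log axis, for the uninjured (blue) and NaOH-injured (red) library; points are levels of 1 library each and bars exact Poisson 95% intervals, many narrower than the point. Krt12 stood at 19620 against 27.0 and Clu at 190.0 against 3072.

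Other genes that were far lower in the injured epithelium were the water channel Aqp5, 43.5-fold (42.4 to 44.8), the mitochondrial protein gene Mgarp, 136-fold (129.9 to 142), the natriuretic peptide gene Nppb, 34.5-fold (31.0 to 38.4), the synaptic scaffold gene Homer2, 42.4-fold (38.2 to 47.1), and the desmosomal cadherin Dsg1a, 22.6-fold (20.5 to 24.9). Ces1d, Guca1a, Ly6g6c, Fam83a and Erich5 were 22.0-fold to 49.98-fold lower. Krt17, a keratin of wounded epithelium, reached 3415 CPM against 129.8, 26.3-fold (25.8 to 26.9). Gpha2, a limbal stem cell marker, stood at 1950.2 against 176 CPM, and the basal keratins Krt14 and Krt15 8306 against 2764 and 5827 against 1788 CPM. The limbal-like cluster 15, of 278 uninjured and 36 injured cells, held Gpha2 at 2742, Krt14 at 7844 and Krt15 at 3411 CPM. The class ratios of these genes may therefore mix level and makeup. Krt5, the partner of Krt14, was at 3278 against 6038 CPM, a log2 ratio of -0.88. Conjunctival keratins were also higher, Krt19 14.5-fold (14.0 to 15.0), Krt4 10.9-fold (10.6 to 11.2) and Krt7 48.3-fold (44.6 to 52.3). The antimicrobial genes Ltf (lactoferrin) and Wfdc18 stood at 256 and 902 CPM against 1.14 and 2.39, the growth factor carrier Igfbp3 at 110.3 against 1.03, the transcription factor gene Sox4 at 125 against 4.35, and Actn1, which encodes the actin crosslinker alpha-actinin 1, at 103 against 1.83. Ppbp, the chemokine CXCL7 known from platelets (ENSMUSG00000029372; chromosome 5, 90768518 to 90770063, plus strand), stood at 697 against 0.380 CPM, 1831-fold higher (1267 to 2756). Sprr2a3 and Serpinb3a belong to families of near-identical copies, so their higher counts (113 against 0.122 and 473 against 29.4 CPM) may be shared with other members. Under the stricter cell filter the log2 ratio of Ltf was 11.59 in place of 7.81 and that of Krt7 6.47 in place of 5.59; with each cell weighted alike those of Wfdc18 and Ppbp were 7.16 in place of 8.56 and 9.83 in place of 10.84.

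Growth factors of the EGF receptor differed in both directions in the epithelium. Ereg (epiregulin) and Areg (amphiregulin) were 17.5-fold (16.1 to 19.2) and 5.01-fold (4.92 to 5.10) higher, and Nrg1 and Epgn 3.63-fold (3.48 to 3.79) and 3.09-fold (2.97 to 3.22) lower. Immediate early genes, which respond within minutes to growth factors, stress and tissue dissociation, were lower in 7 of 15 measured members, with none at least 2-fold higher and a median log2 ratio of -0.79 (-1.52 to -0.42; percentile 0). Socs3 was 6.12-fold (5.92 to 6.33), Zfp36 3.90-fold (3.81 to 3.98) and Fos 3.53-fold (3.5002 to 3.57) lower. Glycolysis genes had a median of 0.80 (0.48 to 1.18; percentile 100), with 3 of 13 at least 2-fold higher, among them Pgk1 (phosphoglycerate kinase) at 277 against 122 CPM. The list of wound keratins and cornified envelope genes held 6 of 15 higher members and 1 lower, median 0.64; apart from Krt17 its abundant members differed less, Krt16 at 494 against 914 CPM. Mitochondrially encoded transcripts had a median of 0.65 (0.22 to 0.91), led by the cytochrome oxidase gene mt-Co1 at 7511 against 3235 CPM, and the median mitochondrial share per analysed cell was 3.41% injured against 2.28% uninjured. The oxidative stress list had 4 of 10 higher, 2 of them above free RNA levels, and 1 lower. Its median was 0.38, or 0.18 without members at free RNA levels, with the glutathione synthesis gene Gclm 2.75-fold higher (2.65 to 2.85). Junction genes were at least 2-fold lower in 1 of 13, median -0.36. Of 8 MHC class I genes 1 was higher, at a free RNA level, median 0.30, and of 14 cell death genes 5, 2 of them above free RNA levels, median 0.38. Heat shock genes (0.19, 1 higher and 2 lower of 9) and cell cycle genes (-0.09, 1 lower of 15) had medians near 0.

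Different clusters held most of the epithelium in the libraries. Uninjured cells lay in the corneal-like clusters 1, 4, 7, 8, 12 and 18, and injured cells in the limbal-like clusters 0, 2, 5 and 10 and the conjunctival-like cluster 9. Each name is the highest of the corneal, limbal, conjunctival and goblet marker scores of the cluster. The corneal score includes Krt12, Slurp1, Aldh3a1, Upk1b and Pax6, which were lower in the injured epithelium. The names are thus not a separate sign of where the injured cells came from. With 1 library per group, a cluster mostly of 1 library may be that library and not a type. Cluster 20, conjunctival-like, held 76 uninjured and 73 injured cells, and there Krt12 stood at 9958 against 5.78 CPM and Clu at 129 against 1032 CPM. Slurp1 stood there at 10638 CPM against no UMI, Krt4 at 11.6 against 2829, Krt19 at 56.9 against 2128 and Krt13 at 3945 against 11836 CPM. In the corneal-like cluster 4, with 909 uninjured and 16 injured cells, Krt12 stood at 29717 against 2.53 CPM, Slurp1 at 6133 CPM against no UMI, Krt4 at 267 against 2852 and Krt19 at 167 against 1478 CPM. In the limbal-like cluster 15, with 278 uninjured and 36 injured cells, Krt12 stood at 3982 CPM against no UMI, Aldh3a1 at 4696 against 647 CPM, and Pax6 at 220 against 195 CPM.

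In the stroma the injured library held high levels of acute-phase, antimicrobial and chemoattractant genes. The libraries held largely different sub-clusters of this class, given below, so its ratios may mix level and makeup. Saa3, an acute-phase serum amyloid gene (ENSMUSG00000040026; chromosome 7, 46711998 to 46715700, minus strand), stood at 1065 CPM (1045 to 1085) against 1.16 CPM (0.239 to 3.39; 3 UMIs), and Timp1, which inhibits matrix metalloproteinases, at 2136 CPM (2108 to 2165) against 10.1 (6.57 to 14.7), 213-fold higher (145 to 325). Lcn2, which binds bacterial iron carriers, was 168-fold (81.7 to 419), the protease inhibitor gene Slpi 145-fold (66.4 to 394), the pentraxin gene Ptx3 97.9-fold (41.9 to 302), and the serpin gene Serpina3n, at 2545 CPM, 46.0-fold (39.1 to 54.6) higher. Csf3, the granulocyte colony-stimulating factor, had no UMI in the uninjured stromal-like cells and 108 CPM in the injured, a ratio with a lower limit of 75.8. Point ratios have counts under 3 over a class set to 3 throughout. The cytokine gene Lif was 48.6-fold higher (18.9 to 179). Of 11 measured alarmin and antimicrobial genes 8 were higher, median 3.89 (0.62 to 7.40), and of 10 inflammatory cytokine genes 7, median 2.49 (0.32 to 5.60); no member of either was at least 2-fold lower, and both lay at percentile 100. All 5 measured neutrophil chemokine genes were higher, 1 of them above free RNA levels, median 3.68, with Cxcl5 at 1946 against 163 CPM and Cxcl1 at 816 against 205 CPM. Cxcl2, at 624 against 6.96 CPM, lay far below its 20034 CPM in the injured neutrophil-like cells, whose free RNA may add to it. Monocyte and lymphocyte chemokine genes were higher in 6 of 13, median 1.07, among them Ccl7 26.8-fold (20.02 to 36.6), Ccl2 14.3-fold (12.6 to 16.3) and Cxcl14 12.96-fold (11.8 to 14.3). NF-kappaB target genes were higher in 4 of 12, median 0.77, led by Ptgs2, the inducible cyclooxygenase, at 1161 against 213 CPM, and Nfkb1 itself at 244 against 47.9 CPM. With every cell thinned to 1000 UMIs the medians were 1.40 (0.50 to 5.98) for alarmin, 1.51 (-0.09 to 3.66) for inflammatory cytokine, 2.35 (0.59 to 6.29) for neutrophil chemokine and 0.76 (-0.41 to 4.11) for monocyte chemokine genes. Without members at free RNA levels the monocyte chemokine median was 3.70 and the alarmin median 7.29, and with 15 principal components in the clustering the log2 ratio of Timp1 was 10.61 in place of 7.73.

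**Figure D3:**
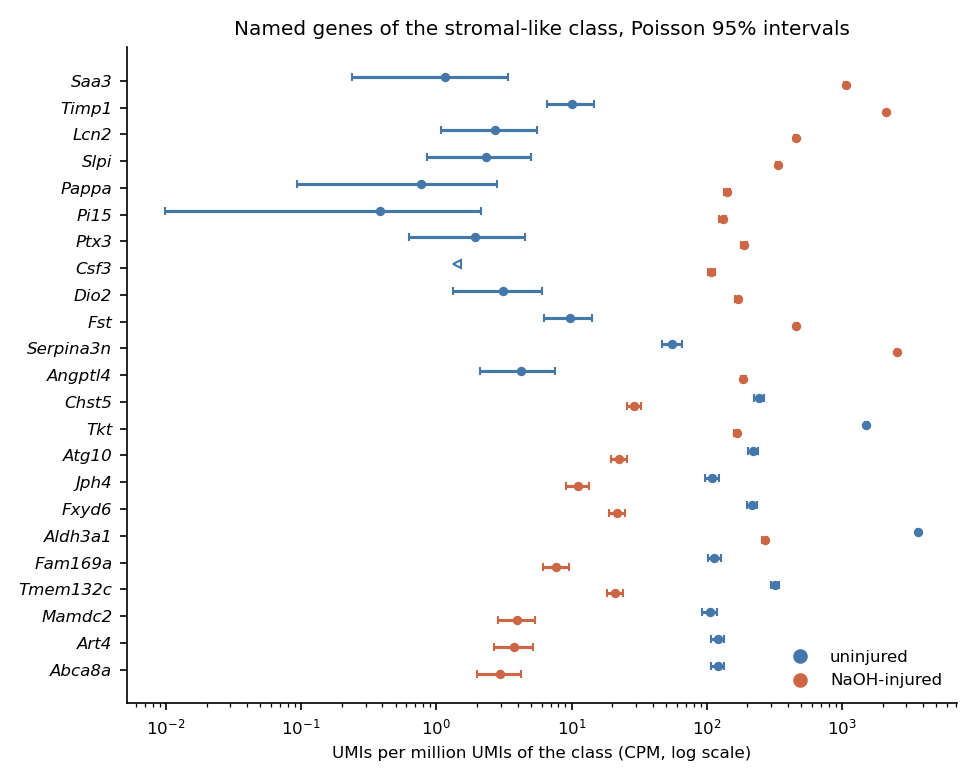
Levels in stromal-like cells of the named genes with the largest ratios in each direction, in CPM on a log axis, for the uninjured (blue) and NaOH-injured (red) library; points are levels of 1 library each, bars exact Poisson 95% intervals, and the open triangle for Csf3 the upper limit of a count of 0. Saa3 stood at 1065 injured against 1.16 uninjured.

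Matrix genes divided by kind. Mmp3, stromelysin 1, stood at 17529.8 against 767 CPM, 22.9-fold higher (21.9 to 23.9), and 11 of 16 matrix proteases and inhibitors were higher, median 1.84 (0.92 to 3.11; percentile 100), Mmp14 at 228 against 52.6 CPM. Fibrillar matrix genes were higher in 7 of 14, median 0.92, or 0.40 at clustering resolution 2, with the collagen gene Col3a1 18.6-fold (17.2 to 20.2), tenascin C (Tnc) 9.53-fold (7.93 to 11.6), the collagen crosslinker gene Lox 7.78-fold (7.09 to 8.55) and periostin (Postn) 6.87-fold (5.76 to 8.27) higher, while Col1a1, the main corneal collagen gene and outside the naming rule, was at 9829 against 9732 CPM. Basement membrane genes were higher in 7 of 13, median 1.55, or 0.57 without members at free RNA levels, with the laminin gene Lamb1 10.0-fold higher (7.21 to 14.4). The cornea's proteoglycan genes were lower or near equal: Kera (keratocan), the keratocyte marker that also helped to name the class, stood at 138 against 3567 CPM, 25.8-fold lower (24.4 to 27.3). Dcn (decorin) stood at 16342 against 46763 CPM, and Lum (lumican) at 4319 against 6772 CPM, with 2 of 8 at least 2-fold lower and a list median of -0.45. Chst5, the sulfotransferase of corneal keratan sulfate, was 8.40-fold lower (7.30 to 9.69), as were the transporter gene Abca8a 40.5-fold (27.8 to 61.0), Art4 32.1-fold (22.9 to 46.2) and Mamdc2 26.5-fold (19.0 to 37.9). Aldh3a1 and Tkt were 13.6-fold and 9.12-fold lower; epithelial Krt12, a measure of free RNA, stood at 1039 CPM in the uninjured stromal-like cells and 0.794 in the injured. The myofibroblast list had 6 of 8 members higher, 2 of them above free RNA levels, median 1.63, but Acta2 (smooth muscle actin), at 212 against 5.03 CPM, stood at under 25% of its level in mural-like cells.

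Growth factor and metabolic genes of the stroma differed as well. Fgf7, the keratinocyte growth factor, was 13.9-fold (8.94 to 22.8), the receptor gene Pdgfra 2.77-fold (2.48 to 3.09), and follistatin (Fst), which binds activin, 47.6-fold (32.2 to 73.6) higher. Of the PDGF and FGF pathway genes 7 of 14 were higher and 2 lower, median 0.79, or 0.02 with every cell thinned to 1000 UMIs. The angiopoietin-like gene Angptl4 was 44.0-fold (24.5 to 88.2) and the deiodinase gene Dio2 54.7-fold (27.7 to 127) higher. Pappa, a protease that frees insulin-like growth factors, had 2 UMIs in the uninjured class and 141 CPM in the injured, a ratio with an interval of 50.4 to 1508. Among anti-angiogenic genes Chil1, a chitinase-like gene, was 32.2-fold higher (27.1 to 38.6) and Serpinf1, the pigment epithelium-derived factor, 2.90-fold lower (2.82 to 2.98), with 4 of 9 higher, 1 lower and a median of 0.92. Glycolysis genes were higher in 6 of 13, median 0.96, Pgk1 at 325 against 101 CPM. Cell cycle genes were higher in 13 of 15, median 2.29, although 2 of them reached 25% of the level in the highest class. Interferon response genes (1 higher and 4 lower of 12, median -0.51), immediate early genes (3 lower of 15, -0.57), unfolded protein response genes (2 lower of 10, -0.53) and heat shock genes (2 lower of 9, -0.07) had negative medians. Cluster 13 held 418 of the 459 uninjured stromal-like cells and cluster 6 802 of the 803 injured. A sub-cluster led by Kera and Angptl7 held 341 uninjured and 0 injured cells. Another, led by Cxcl14 and with Col3a1 and Saa3 among its top genes, held 0 and 331. A change of makeup and a change of level in the same cells therefore cannot be told apart in this class. The median depths of the class were 5735 and 11994 UMIs per cell. The injured class also held a corneal endothelial-like sub-cluster of 128 cells (6 uninjured), a trabecular meshwork-like one of 63 (25 uninjured) and an unnamed one of 274 cells led by Chil1 (0 uninjured). Without these, an alternative chosen after seeing the data, the medians were 0.16 for glycolysis, 0.12 for anti-angiogenic, 0.97 for cell cycle and 3.54 for inflammatory cytokine genes.

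Mural-like cells, the pericytes and smooth muscle cells around vessels, held fewer interferon-induced transcripts in the injured library (87 cells) than in the uninjured (58 cells). Isg15, a ubiquitin-like interferon-induced gene, stood at 135 CPM (108 to 166) against 1447 (1244 to 1673), 10.8-fold lower (8.29 to 14.0), Iigp1, an interferon-induced GTPase, 6.87-fold (5.36 to 8.83) and the chemokine gene Cxcl9 11.9-fold (4.63 to 34.2) lower. Of 7 measured interferon response genes 5 were lower and none was at least 2-fold higher, median -2.44 (-3.43 to 0.53; percentile 0); with each cell weighted alike the median was -1.31. Contractile and matrix genes were higher: Actg2 (enteric smooth muscle actin) 12.4-fold (4.19 to 60.8), Acta2 2.76-fold (2.48 to 3.08) and Postn 5.00-fold (2.88 to 9.49), with 7 of 13 fibrillar matrix genes higher, median 1.25, and 5 of 10 myofibroblast genes, median 1.01. The cytokine gene Il11 and the chemokine gene Ccl7 had 1 UMI each in the uninjured class against 298 and 350.1 CPM in the injured, and Stc1, a secreted glycoprotein, was 8.27-fold higher (3.17 to 30.7). Thinned to 1000 UMIs per cell the log2 ratios were 1.71 for Il11, 1.505 for Stc1 and -1.61 for Cxcl9 in place of 3.64, 3.05 and -3.57. The value of Il11 is a lower limit, as its uninjured count was set to 3 after thinning too. Cell cycle genes were higher in 9 of 15, median 1.43, or 0.50 with every cell thinned to 1000 UMIs. Immediate early genes were lower in 11 of 15, median -1.21, and heat shock genes in 5 of 9 with 1 higher, median -1.08. Rasl11a, a Ras-like gene, was 16.8-fold lower (10.8 to 26.8). The mural-like sums were small, 125792 uninjured and 654067 injured UMIs, and scaling by trimmed means moved all log2 ratios by -0.16 here, -0.19 in Schwann-like and -0.15 in vascular endothelial-like cells.

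Schwann-like cells, the glia of corneal nerves (54 uninjured and 96 injured cells), held injury-associated transcripts in the injured library. Gap43, a growth cone gene of regenerating nerves, stood at 369 CPM (305 to 442) against 28.4 (3.44 to 103; 2 UMIs), and Postn at 662 CPM (576 to 758) against no UMI, a ratio with a lower limit of 12.5. The proliferation genes Mki67 and Top2a had no UMI in the uninjured class and 356 and 325 CPM in the injured, ratios with lower limits of 6.69 and 6.09, and 9 of 11 cell cycle genes were higher, median 1.56 (0.41 to 2.93). With every cell thinned to 1000 UMIs the median was 0.66 (-0.34 to 1.503), and the log2 ratios of Mki67 and Top2a were 1.503 each in place of 3.06 and 2.93. These 2 ratios are lower limits, as the uninjured counts were set to 3 after thinning too. Fibrillar matrix genes were higher in 7 of 8, median 2.04, and basement membrane genes in 3 of 8, median 1.47. The Col1a1 and Col3a1 counts lay under 25% of those in stromal-like cells. With doublets marked by the caller's own threshold the basement membrane median was 0.34, and with no minimum of UMIs per member -0.09. The integrin gene Itgb8 was 6.36-fold (2.11 to 31.5) higher. Isg15 was 9.34-fold lower (4.78 to 19.1), Pde4b, a cyclic AMP phosphodiesterase gene, 9.46-fold lower (4.27 to 22.5), and 6 of 15 immediate early genes were lower, median -0.79, as were 2 of 7 heat shock genes, median -0.63.

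Vascular endothelial-like cells, a class of 42 uninjured and 212 injured cells added after seeing the data, carried proliferation genes in the injured library. Mki67 stood at 166 CPM (148 to 184) against 13.1 (1.59 to 47.5; 2 UMIs) and Top2a at 163 against no UMI, a ratio with a lower limit of 6.67. Thinned to 1000 UMIs per cell their log2 ratios were 0.25 and 0.18 in place of 3.07 and 3.04. Both are lower limits, as uninjured counts under 3 were set to 3 after thinning too. Of the cell cycle genes 14 of 15 were higher, median 1.81 (1.53 to 2.69). With every cell thinned to 1000 UMIs the median was -0.70 (-1.19 to 0.25). Uninjured counts under 3 were set to 3 in that small sum, so the sign does not show a lower level after injury. At the same depth 44 of 207 injured and 0 of 39 uninjured cells had at least 2 cell cycle genes. The basement membrane genes Col4a1 and Lamb1 were 4.78-fold (3.76 to 6.16) and 4.21-fold (2.02 to 10.5) higher, with 4 of 11 higher and a median of 0.60. The median was 0.26 with no minimum of UMIs per member and 1.70 with a minimum of 100. Genes of sprouting vessels, such as the peptide gene Apln (apelin, 2 UMIs uninjured and 109.7 CPM injured), its receptor gene Aplnr, 5.39-fold (2.08 to 19.9), and Mcam, 3.93-fold (1.89 to 9.85), were higher in 5 of 11 with 1 lower (Robo4) and a median of -0.02. The median was 0.94 without members at free RNA levels, 1.98 with a minimum of 100 UMIs per member and -0.29 thinned. In the VEGF list Flt4, also a top gene of the lymphatic endothelial-like sub-cluster within this class, was 4.67-fold higher (1.80 to 17.3), Flt1 2.15-fold lower (1.79 to 2.58) and Kdr, the main VEGF receptor gene, at 295 against 434 CPM, median -0.19. Adhesion genes through which leukocytes attach were lower in 4 of 8 and higher in 1, median -0.76, or -0.11 with every cell thinned to 1000 UMIs. E-selectin (Sele) was 6.63-fold (5.63 to 7.78), P-selectin (Selp) 4.45-fold (4.06 to 4.87) and Icam1 2.83-fold (2.30 to 3.46) lower (Sele log2 -1.24 thinned, in place of -2.73), and Il6 8.62-fold (6.55 to 11.3) lower. Foxc1, a forkhead transcription factor gene of eye vessels, was 5.46-fold lower (3.42 to 8.50) and the flow-responsive gene Klf2 2.82-fold (2.22 to 3.55), with 4 of 13 endothelial transcription factor genes lower, 1 higher and a median of -0.89, or -0.32 with each cell weighted alike. Notch1 and its target Hes1 were 2.19-fold (1.60 to 2.96) and 2.29-fold (1.67 to 3.10) lower, 3 of 9 Notch pathway genes lower and 1 higher, median -0.89, or -0.26 with each cell weighted alike. Immediate early genes were lower in 12 of 15, median -1.35, interferon response genes in 4 of 14, median -0.60 (-0.14 with each cell weighted alike), and heat shock genes in 4 of 9 with 1 higher, median -0.83; glycolysis genes had a median of 0.61, or -0.05 thinned. The lymphatic genes Lyve1 (270.4 CPM) and Ccl21a belonged to a lymphatic endothelial-like sub-cluster of 17 injured cells and no uninjured cell, and the log2 ratio of Lyve1 was 1.01 thinned, in place of 3.78. The thinned value is a lower limit, as no UMI of Lyve1 was counted in the uninjured class.

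Macrophage or monocyte-like cells, 17 uninjured and 361 injured and likewise added after seeing the data, carried transcripts of some repair-associated genes after injury. Spp1 (osteopontin; ENSMUSG00000029304; chromosome 5, 104435118 to 104441050, plus strand) stood at 1763 CPM (1704 to 1823) against 1 UMI, a ratio with an interval of 18.9 to 4164, and Arg1 (arginase 1) at 748 CPM (709 to 787) against none, a ratio with a lower limit of 12.1. The lysosomal and tissue-remodelling genes Ctsk and Mmp9 had no UMI uninjured and 596 and 647 CPM injured. Spp1 stood higher in injured neutrophil-like cells, at 5394 CPM, and Mmp9 was among the markers listed for neutrophils. Free RNA of neutrophil-like cells may add to both. Thinned to 1000 UMIs per cell the log2 ratios were 0.27 for Ctsk, 0.59 for Mmp9 and 1.90 for Arg1 in place of 3.57, 3.69 and 3.90. All are lower limits, as the uninjured counts of 0 were set to 3 in the much smaller thinned sum too. Glycolysis genes were higher in 8 of 13, median 1.46 (-0.58 to 2.33), or 0.72 thinned to 1000 UMIs, with the pyruvate kinase gene Pkm 5.04-fold higher (2.74 to 10.5). Repair macrophage genes were higher in 6 of 14 with 1 lower, median 0.61, which turned to -0.12 with every cell thinned to 1000 UMIs. The thinned median includes members, such as Arg1 and Spp1, whose uninjured counts were set to 3. Lipid handling genes were higher in 5 of 11 with 1 lower, median 0.53. All 6 measured MHC class II genes, which present antigen, were lower, median -1.73 (-2.06 to -1.14), with Cd74 at 4224 against 17646 CPM. The class also held a dendritic-like sub-cluster led by MHC class II genes, of 6 uninjured and 109 injured cells, and a T, NK or innate lymphoid-like one of 3 and 16. Inflammatory macrophage genes were lower in 6 of 9 and higher in 1, median -2.08, among them Tnf 6.88-fold (4.23 to 10.8) and Ccl3 4.81-fold (3.77 to 6.06), and monocyte and lymphocyte chemokine genes in 8 of 12 with 2 higher, median -1.41. Immediate early genes were lower in 8 of 15, median -1.07, and heat shock genes in 2 of 9, median -0.66. Over all 7381 measured genes of this class the median log2 ratio was -0.70. List medians of the class are thus to be read against that value and not against 0, and the heat shock median lay near it. The uninjured cells included mast and Langerhans cell transcripts absent or rare in the injured: Mcpt4, a mast cell protease gene, had 49 UMIs against 0, Cma1 48 against 0, and Cd207 (langerin) 17 against 9. With doublets kept the log2 ratios of Mcpt4 and Cma1 were -3.47 and -3.94 in place of -9.05 and -9.02. Clustering each library on its own gave this class 5.25% of uninjured cells, moved the repair median to 3.36, moved the lipid handling median to 2.76, and turned the heat shock median to 0.62, the chemokine median to 2.07 and the inflammatory macrophage median to 0.87.

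**Figure D4:**
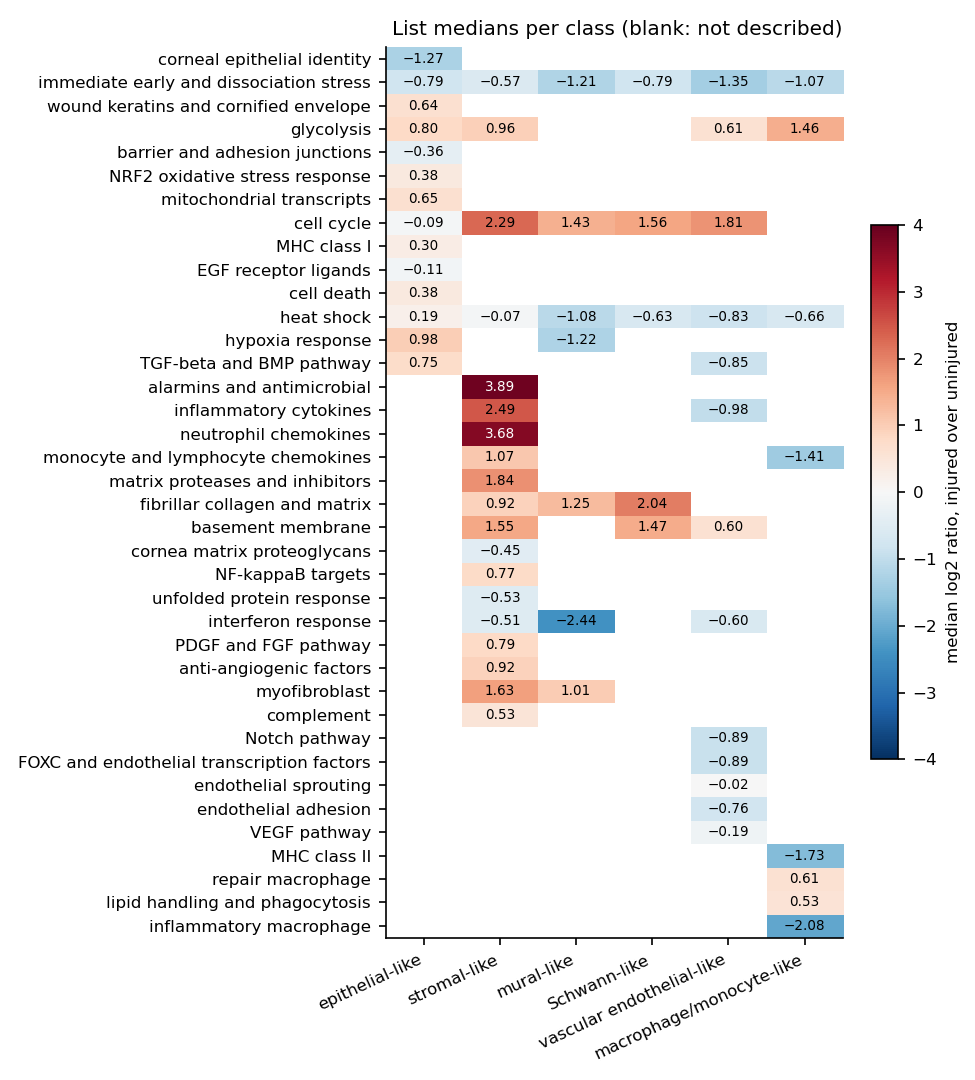
Median log2 ratio, injured over uninjured, of the gene lists described for each cell class (color scale and printed value; blank where a list was not described), from 1 library per group. Inflammatory and alarmin lists of the stroma reached 2.49 and 3.89, and immediate early genes had negative medians in all 6 classes.

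The 1020 injured neutrophil-like cells had no counterpart to compare with in the uninjured library. Among the listed and named genes measured in them the highest included the alarmins S100a9, 30116 CPM (29767 to 30469), and S100a8, 27845 CPM (27509 to 28184), which also helped to name the class, and the chemokine genes Cxcl2, 20034 CPM (19749 to 20322), Ccl4, 9883 CPM (9683 to 10086), and Ccl3, 7036 CPM (6867 to 7207). The cytokine gene Il1b stood at 3631 CPM (3511 to 3755) and Spp1 at 5394 CPM (5246 to 5544).

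Levels of 54 ligand and receptor pairs were set side by side by class to describe which cells carried each partner. Cxcr2, the neutrophil chemokine receptor, had 421 CPM in injured neutrophil-like cells, while its ligand Cxcl5 was highest in stromal-like cells (1946 injured against 163 CPM uninjured), Cxcl1 in mural-like cells (3541 against 3339) and Cxcl2 in the neutrophil-like cells themselves. The receptor Csf3r stood at 744 CPM in neutrophil-like cells and its ligand Csf3 at 201 CPM in vascular endothelial-like cells, against 394 uninjured. Csf1, which sustains macrophages, was highest in injured neutrophil-like cells (1380.0 CPM), and its receptor Csf1r in macrophage or monocyte-like cells (439.6 against 368 CPM). Ccl2 was highest in injured mural-like cells (2935 against 906 CPM in the same class) and its receptor Ccr2 in macrophage or monocyte-like cells (217 against 167). Areg and the receptor Egfr were both highest in the epithelium, Areg at 959 against 191 and Egfr at 62.6 against 77.8 CPM. Gas6, the ligand of Axl, was highest in injured stromal-like cells at 724 against 49.1 CPM there. Vegfa was highest in stromal-like cells in both libraries (140.3 against 82.0 CPM), and Wnt5a, also stromal, stood at 298 against 777 CPM.

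The share of cells with transcripts of at least 2 cell cycle genes, after thinning every cell to 1000 UMIs, was higher in the injured library in vascular endothelial-like cells, 21.3% (15.9 to 27.5, 44 of 207 cells) against 0 of 39 cells (upper limit 9.03%). It was 2.88% (1.84 to 4.29) against 0.222% (0.00561 to 1.23) in stromal-like cells. The intervals overlapped in mural-like cells, 20.2% (12.3 to 30.4) against 7.27% (2.02 to 17.6), in Schwann-like cells, 13.2% (7.004 to 21.9) against 2.33% (0.0589 to 12.3), and in epithelial-like cells, 13.7% (12.8 to 14.6) against 14.1% (13.2 to 15.0). Macrophage or monocyte-like cells had 6.41% (4.06 to 9.55) injured against 0 of 17 uninjured cells (upper limit 19.5%). Neutrophil-like cells, which do not divide, had 1.56% (0.427 to 3.95), and the stromal share in the injured library lay within that interval. They give a rough background only, as 256 of 1020 cells were deep enough to be used. With at least 3 genes they had 0% (upper limit 1.43%) and the injured stromal-like cells 1.25% (0.603 to 2.29). Median depths before thinning were 2981 uninjured and 6724.5 injured UMIs in vascular endothelial-like cells, 5735 and 11994 in stromal-like cells and 852.5 in neutrophil-like cells. Cells under 1000 UMIs were left out, 764 of the neutrophil-like and at most 35 of any other class and library. Without thinning the shares were 52.8% against 23.8% in vascular endothelial-like and 36.1% against 12.6% in stromal-like cells.

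**Figure D5:**
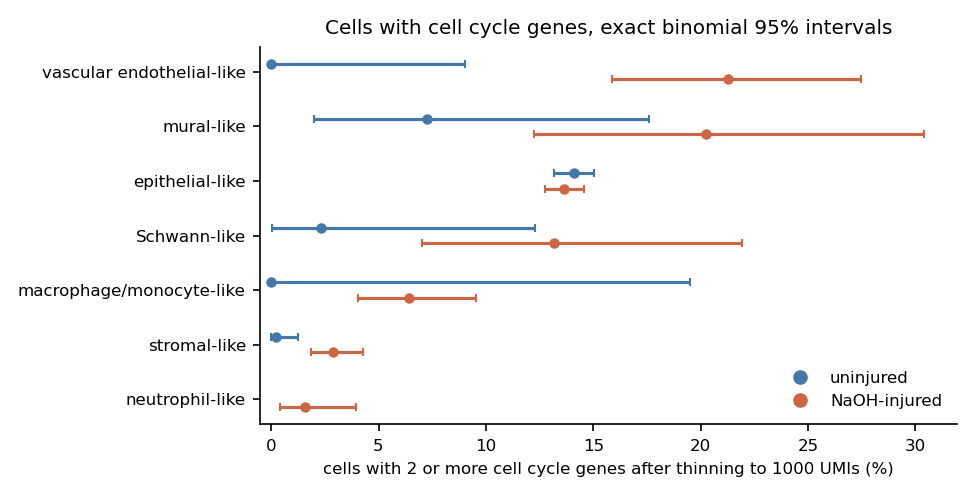
Percent of cells with at least 2 cell cycle genes detected after thinning each cell to 1000 UMIs, by class, for the uninjured (blue) and NaOH-injured (red) library; points are shares in 1 library each and bars exact binomial 95% intervals. Vascular endothelial-like cells had 21.3% against 0, and epithelial-like cells 13.7% against 14.1%.

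Summed over all cells, which mixes levels with the makeup of each library, Krt12 stood at 18952.8 CPM uninjured and 22.7 CPM injured, Saa3 at 0.308 and 116 CPM, S100a8 at 2.63 and 306 CPM, and Mmp3 at 28.7 and 1909 CPM.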

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

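The tests of depth, limbal cells and swapped labels for the corneal genes were chosen only after the result was seen. So were all tests for the immediate early genes. The test of conjunctival cells was chosen before, but its check on Slurp1 was not part of what was set then.

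The inflammatory cytokine list differed between classes: its median log2 ratio was 2.49 in stromal-like and -0.98 in vascular endothelial-like cells, a difference of 3.46. It is listed because the medians lie on opposite sides of 0. The difference was not tested, the vascular class was added after seeing the data, and 4 list members were measured there. With cells thinned to 1000 UMIs the stromal median was 1.51 (-0.09 to 3.66).

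Krt12 and other corneal genes were far lower in the injured epithelium. A lower depth of injured epithelial-like cells is argued against by their median UMIs, 11672.5 against 11211 in the uninjured. The lower log2 ratio of Krt5 and Krt14 was -0.88, far from that of Krt12. That ratio cannot test depth, since a loss alike for all genes scales out of CPM. Swapped labels are argued against by the 0.0295% of neutrophil-like cells in the library labelled uninjured. Conjunctival cells in place of corneal ones cannot be told apart from a response of the epithelium to the injury. Both limits set beforehand against this explanation were met in the shared conjunctival-like cluster. Krt12 was 1724-fold lower there, and 76.3% of its uninjured cells (65.2 to 85.3) had Krt12 above the free RNA level. A check outside those limits set this result aside, as it is unsettled that the uninjured cells were conjunctival. They held Slurp1 at 10638 CPM, against 4432 CPM in the whole uninjured class. Krt13 stood at 3945 CPM in them and Krt19 at 56.9 CPM, against 2128 CPM in the injured cells. Limbal cells in place of corneal cells stay open too. In shared limbal-like clusters 29.7% of uninjured cells (24.7 to 35.0) and no injured cell had Krt12 above that level. These shares cannot decide the question. Low Krt12 itself counted towards naming a cluster limbal-like and not corneal-like. The free RNA level was also high, the 95th percentile of Krt12 in uninjured non-epithelial cells, 4528 CPM. It was set from the uninjured library, whose free RNA held far more Krt12 than that of the injured. The 16 injured cells of the corneal-like cluster 4, with Krt12 at 2.53 CPM, held Krt19 at 1478 CPM against 167 CPM in its uninjured cells. A change of makeup, from loss of corneal cells or from dissection, could therefore account for part or all of the difference.

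Immediate early genes had a list median below 0 in 6 of 6 classes. A different depth per cell is argued against in the epithelium, where median depths were 11211 and 11672.5 UMIs at a list median of -0.79 (-1.52 to -0.42). It is also argued against by medians after thinning to 1000 UMIs. These were -1.14 (-1.32 to -0.77) in mural-like, -0.69 (-1.34 to -0.34) in Schwann-like and -1.13 (-1.36 to -0.55) in vascular endothelial-like cells. Low uninjured counts in the thinned sums were raised to a minimum, which lowers a ratio. How many members of this list that touched is not shown. Depth cannot be told apart in stromal-like cells, at -0.39 (-0.77 to 0.21) thinned, as the interval spans 0. Nor can it be told apart in macrophage or monocyte-like cells, at -1.06 (-1.88 to -0.41) thinned. That interval holds -0.70, the median log2 ratio of all measured genes of the class before thinning. A median under 0 therefore cannot decide there. Handling of the tissue that differed between the libraries and the injury itself cannot be told apart: of 5 epithelial clusters held by both libraries the median lay under 0, interval included, in 2 and above 0 in 2, and each group is 1 dissociation.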

How the results depend on the processing

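The assumed doublet rate, the classes of at least 10 cells and the sub-clusters left out were chosen only after the data were seen; the caller's own threshold, which that rate replaced, was run as an alternative. Each alternative altered 1 step of the processing, the stricter filter all 3 of its limits at once. The cause of a move was not tested. Of 140 named gene ratios 138 kept their sign under all alternatives run, as did 58 of 66 list medians; 8 of the medians took the other sign in at least 1 alternative. Of 25 thinned list medians with an interval that excluded 0, 17 kept such an interval after thinning. The other 8 were the inflammatory cytokine, monocyte chemokine, glycolysis and cell cycle lists of the stroma, the cell cycle lists of mural-like, Schwann-like and vascular endothelial-like cells and the chemokine list of macrophage or monocyte-like cells. Of 1079 list medians recomputed 1060 stayed within their interval, 17 moved and 2 reversed; of 1884 gene ratios 1671 stayed, 211 moved and 2 reversed. Shares stayed within their interval in 118 of 144 recomputed values. No paired analysis was possible because each group has 1 library.

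Shares in percent, uninjured then injured where both moved, were 86.2 and 76.7 for epithelial-like, 3.23 for injured neutrophil-like and 3.94 and 0.991 for unnamed cells under the stricter filter, which removes shallow cells. With no filter they were 74.4 and 67.7 for epithelial-like and 16.6 and 2.30 for unnamed cells. With 15 principal components they were 83.3 for uninjured epithelial-like and 4.80 and 8.26 for stromal-like cells. There the share of unnamed cells, uninjured, was 9.37, and injured 1.37. At resolution 2 they were 0.0886 and 2.47 for macrophage or monocyte-like, 8.06 for injured stromal-like and 2.35 for injured unnamed cells. With each library clustered on its own they were 5.25 and 2.71 for macrophage or monocyte-like, 0 for uninjured neutrophil-like and 8.71 and 1.58 for unnamed cells. Injured neutrophil-like cells made up 11.4 with doublets kept and 11.4 with the automatic threshold, which gave 0.611 for injured unnamed cells.

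The stromal cell cycle median was 0.97 with other sub-clusters left out, 1.81 with the stricter filter, 1.62 at resolution 2, 2.66 with the automatic threshold, 1.60 as a mean over cells and 0.76 thinned. The stromal monocyte chemokine median was 3.70 without members at free RNA levels. The mural immediate early median was -1.37 with TMM scaling. The mural cell cycle median was 0.50 thinned and 2.76 with a minimum of 100 UMIs. In vascular endothelial-like cells the cell cycle median was 1.33 and the inflammatory cytokine median -0.53 as means over cells. Thinning gave a cell cycle median of -0.70 and a log2 ratio of Prnd of -0.41, which the counts above take as reversed. Counts under 3 in the thinned sums were set to 3, which lowers a ratio whose uninjured count is under 3. The negative signs therefore do not show a lower level in the injured cells. An effect of depth on these values was not excluded. In macrophage or monocyte-like cells clustered per library the chemokine median reversed to 2.07 and Ifitm1 to -1.46. There the medians were -2.22 for MHC class II, 3.36 for repair, 2.76 for lipid handling, 0.87 for inflammatory and 0.62 for heat shock genes.

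Cycling shares in percent, uninjured then injured where both moved, were as follows. With at least 3 genes they were 8.44 and 7.08 in epithelial-like and 0 and 1.25 in stromal-like cells. They were 0 in uninjured Schwann-like, 1.82 in uninjured mural-like, 11.6 in injured vascular endothelial-like and 0 in injured neutrophil-like cells. Thinned to 2000 UMIs they were 21.4 and 22.6 in epithelial-like and 2.33 and 7.24 in stromal-like cells. In the injured library they were 24.6 in Schwann-like, 12.4 in macrophage or monocyte-like, 33.3 in vascular endothelial-like and 0 in neutrophil-like cells. Not thinned they were 54.5 and 59.4 in epithelial-like, 12.6 and 36.1 in stromal-like and 23.8 and 52.8 in vascular endothelial-like cells. In the injured library they were 22.9 in Schwann-like, 48.3 in mural-like and 24.1 in macrophage or monocyte-like cells.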

Other observations

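The test of Ppbp was chosen only after the result was seen, as were the gene groups described here, which come from the fixed lists.

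Of the hypoxia genes 5 of 12 were higher in the epithelium and 2 lower, median 0.98 (-0.43 to 2.37), or 0.51 without members at free RNA levels, which left 1 higher and 2 lower. Egln3, an oxygen sensor, was 4.21-fold (4.06 to 4.37) and the peptide gene Adm 3.85-fold (3.73 to 3.97) lower. In mural-like cells 4 of 7 were lower and none was higher, median -1.22 (-2.38 to 0.91), with the glucose transporter gene Slc2a1 2.97-fold lower (1.502 to 5.68); with doublets kept the median was -0.49 and with cells thinned to 1000 UMIs -0.39 (-1.61 to 0.39). TGF-beta and BMP pathway genes had a median of 0.75 (-0.11 to 1.42) in the epithelium, with 7 of 18 higher and 2 lower, among the latter the receptor gene Tgfbr1, 2.71-fold (2.57 to 2.85). All 7 higher members lay at free RNA levels, and without such members the median was 0.35. In vascular endothelial-like cells the median was -0.85 (-1.80 to 0.50), with 5 of 13 lower, led by the BMP target genes Id1, 4.85-fold (4.26 to 5.52), and Id3, 3.49-fold (3.10 to 3.93), and by Smad7, 4.05-fold (3.10 to 5.23), which restrains the pathway.

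Complement genes of the stroma had 4 of 10 higher and 2 lower, median 0.53 (-2.10 to 3.54). C1qb and C1qc, made by macrophages, were the lower members. The median was 2.47 with other sub-clusters left out and 2.02 with 15 principal components.

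Ppbp in the injured epithelium may be made there, a hypothesis that was set against free platelet RNA. Free RNA is shared by all cells of a library, but Ppbp stood at 2714 and 2361 CPM in the conjunctival-like clusters 9 and 20 and at 24.4 to 70.2 CPM in the other epithelial clusters, 111-fold (60.4 to 232) from highest to lowest, which argues against it. Pf4, which platelets also hold, stood at 0 to 14.9 CPM in these clusters. The ratio of Ppbp to Pf4 was 84.7 (78.5 to 91.6) in injured epithelial-like, 4.89 (3.73 to 6.504) in stromal-like, 2.83 (2.005 to 4.05) in neutrophil-like and 0.579 (0.408 to 0.815) in vascular endothelial-like cells. A comparison with macrophages set beforehand was dropped, since they make Pf4 themselves.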
